A study of Mus musculus with 22 samples.

How the data were processed

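Chromatin immunoprecipitation sequencing (ChIP-seq) was carried out on mouse regulatory T cells (Treg cells, the T cells that hold back immune responses and that are defined by the transcription factor Foxp3). Per the labels' protocols, the cells came from spleen and lymph nodes, were stimulated for 1 h with a commercial stimulation cocktail and were fixed with 1% formaldehyde, for 5 min for the histone mark and for 30 min for the transcription factors. Wild-type (WT) cells were set against cells that the series calls IkE5-deficient. The labels do not expand this name, the title names Ikzf1, the gene of the zinc finger transcription factor Ikaros, and how much Ikaros is left in these cells is not known from the lists. Of 22 samples described, 18 came with a peak list. Foxp3, the histone acetyltransferase p300, the calcium-activated factor NFAT1 (Nfatc2) and acetylation of histone H3 at lysine 27 (H3K27ac) had 2 lists per genotype, and Ikaros had 2 lists in WT. The other 4 samples are inputs without a list and are not analysed here.

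The deposited lists hold chromosome, start and end for each peak, with no score, height or p-value and no header. Per the submitters' processing notes the tools named are FastQC, Bowtie2, MACS2, bedtools and HOMER, and the genome build is mm10. Which tool called the peaks, at which threshold and against which input, is not given in the sources used here. Peaks were deposited for each library separately. Peaks of the transcription factors, p300 and Ikaros were 500 bp wide with a single exception in 4 of the lists, so width carries no signal for them. H3K27ac peaks were 500 bp or wider, up to 80869 bp. Read depth per library is unknown, because a list gives no reads. The number of peaks and the covered length stand in for it, and both move with depth, enrichment and the calling threshold as well as with binding.

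Peaks of the 4 libraries of a target were joined into regions where they overlapped by at least 1 bp. A region was called WT only when both WT lists and neither IkE5 list had a peak there, and IkE5 only in the reverse case. With 2 libraries against 2 the smallest 2-sided exact permutation p is 0.333, so no single measure can pass 0.05 by that test. As a yardstick the same region counts were made for the 3 splits of the 4 libraries into pairs. These are the genotype split, the split by library number (both libraries numbered 1 against both numbered 2) and the crossed split (WT 1 with IkE5 2 against WT 2 with IkE5 1). If the number marks a shared preparation, the split by number holds that difference too. Nothing in the labels says that libraries of a group came from separate animals, so the exact permutation and limma p-values measure the spread between libraries, which may be technical. Fisher's exact tests and random lists take genes or regions as the unit, so their p-values and shares measure no spread between libraries or animals. The largest share of identical peak intervals in any of 153 pairs of lists was 0.745%, so no library was counted as a copy of another.

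Regions were assigned to the 21883 protein-coding genes of the RefSeq annotation of GRCm38.p6, the assembly of mm10, when they fell in the gene or within 10 kb of it. That table gives gene start and end without strand, so distances are to the lower-coordinate or higher-coordinate end of a gene, and exons, introns and promoters are not told apart. Fisher's exact test, 2-sided, compared the members of a list that had a WT only or an IkE5 only region with all other genes that had any region of the target, with Benjamini-Hochberg adjustment over 26 tests per target. The 13 lists, with 246 genes, were written before the data were examined. They cover the Treg signature, effector cytokines, the T helper 1 programme, the T helper 2, T helper 17 and follicular programmes, co-inhibitory and exhaustion genes, activation-induced genes, naive and quiescence genes, Ikaros family and corepressor genes, partners of Foxp3 and NFAT, B cell markers, myeloid markers, CD8 T and natural killer (NK) cell markers, and housekeeping genes. Because a gene with many regions has more chances to hold one of either class, each list past 0.05 was also counted over regions and set against 10000 random lists matched on the number of regions per gene. Odds ratios over regions treat neighbouring regions as independent.

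The covered length of H3K27ac in each gene and 10 kb on each side was compared with limma 3.58.1 in R 4.3.3, on log2(scaled covered length + 1000 bp), after scaling to the total covered length of the library, for genes with a mean of at least 1000 bp, with a trended prior and Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate the change of genes with short coverage. List medians were compared with those of 10000 random lists matched on mean covered length. This test was added after the lists had been examined, as were an interferon-induced list of 50 genes and the alternatives named as such in the closing section. Genes named in the text were chosen by a rule set before the data were examined. The rule took Ikzf1, Foxp3, Ifng, Il2, Il2ra, Ctla4 and Pdcd1, up to 10 list genes per target and direction with the widest region, and the nearest genes, within 100 kb, of the 5 widest regions per target and direction. For Foxp3, p300 and NFAT1, whose peaks have a fixed width, a wide region only marks joined peaks that overlap less, so the rule does not rank sites by strength. Further members of a list that passed its test, and the leading genes of the covered-length test, are named as such and were chosen after their values were seen.

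The scripts were tested on simulated data. In 50 simulated sets of p300 lists over 17346 regions, all of the 200 planted IkE5 only regions were found (100%) with 0 called in error, and the list with 7 of 14 genes planted was called in 50 of 50. The region counts check the code alone, since positions were kept apart and unplanted positions drawn as IkE5 only at random were counted as right. They do not measure how many such regions arise without a genotype difference. Without any planted difference the test over genes still called 84 of 1300 other tests, and the count over regions 3, which is why the matched lists stand beside each call. In the simulated H3K27ac covered length of 12718 genes, limma found 0% of 100 genes changed by a log2 size of 1 and 48% of 100 changed by a log2 size of 2, with 2 calls among 12518 unchanged genes. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. Thresholds on a peak score, the strongest peaks, the distance to transcription start sites and motif content need scores, strand or sequence and were not run.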

Results

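The data were peak lists of mouse Treg cells from spleen and lymph nodes after 1 h of stimulation, in WT and in IkE5-deficient cells (written IkE5 from here on), with 2 libraries per genotype and target. The Foxp3 lists held 20608 and 16526 peaks in WT and 21619 and 17265 in IkE5. The p300 lists held 11457 and 8775 peaks in WT and 11670 and 8971 in IkE5. The NFAT1 lists held 7825 and 6850 peaks in WT and 4908 and 3435 in IkE5. The H3K27ac lists held 53032 and 35272 peaks in WT, covering 79.6 and 54.6 Mb, and 47982 and 37152 in IkE5, covering 72.9 and 62.1 Mb. Ikaros, mapped in WT cells only, gave 22297 and 26641 peaks. The title of the series names an association of Ikaros with Foxp3 in gene repression, and the comparisons below address where both factors bind and what differs at those sites in IkE5 cells. All coordinates are of mm10.

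In WT Treg cells most sites of Foxp3, the factor that defines the lineage, also had an Ikaros peak. Peaks of single WT Foxp3 libraries overlapped single Ikaros libraries at 68.1% to 83.2%, and the share was higher for regions found in both libraries. Of 10885 regions with a Foxp3 peak in both WT libraries, 9395 (86.3%) overlapped a region with an Ikaros peak in both Ikaros libraries, and 56.4% of the 16672 Ikaros regions overlapped Foxp3. Ikaros was likewise found at 80.7% of the p300 and 73.1% of the NFAT1 regions of WT. Foxp3 regions placed at random on their chromosomes by 1000 circular shifts overlapped Ikaros at 0.793% on average and 5.19% at most, under the observed share in every shift. The shifts ran over whole chromosomes, so they do not compare with other active sites. Within acetylated chromatin, taken as 27503 regions with H3K27ac in both WT libraries, Ikaros was present at 90.9% of the regions with Foxp3, whereas of those without Foxp3 4809 had Ikaros and 12976 did not, an odds ratio of 26.9 by Fisher's exact test. A wide H3K27ac region can hold both factors at separate sites, and width was not matched. The odds ratio therefore describes shared H3K27ac regions and not shared sites. Both factors lay in H3K27ac regions at most of their sites, 90.8% for Foxp3 and 85.1% for Ikaros, and 44.4% of the Ikaros regions lay within 2 kb of the end of a gene. Among the key genes, Ikaros and Foxp3 peaks coincided 6.25 kb before the lower-coordinate end of Il2ra (chr2:11635997-11636539 for Ikaros), which encodes the high-affinity interleukin 2 receptor chain, beside Pdcd1 (chr1:94035084-94035596), an inhibitory receptor gene, and at the higher-coordinate end of Il2 (chr3:37125849-37126457), the gene of the T cell growth factor that Treg cells do not normally secrete.

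Foxp3 binding was found at most of the same sites in IkE5 cells. The number of Foxp3 peaks was 18567 ± 2886 in WT and 19442 ± 3079 in IkE5 (SD, n = 2 each, ratio 1.05, exact permutation p = 0.667), and 7799 regions had a peak in all 4 libraries. Only 847 regions were WT only and 1117 IkE5 only, against 4048 and 1299 when the same libraries were split by number, so the replicate difference exceeded the genotype difference. At Foxp3 itself (chrX:7579676-7595243), the gene whose product maintains the lineage, the intragenic Foxp3 peak at chrX:7583874-7584397 was present in all 4 libraries, as were the p300 and NFAT1 peaks there. WT only regions included sites in Ikzf3 (chr11:98464563-98465528), which encodes the Ikaros relative Aiolos, in Foxp1, a forkhead factor of resting T cells, in Smad3, a transducer of transforming growth factor beta, and in Stat4, which relays interleukin 12 signals. IkE5 only regions included a site near Il3 (chr11:54271371-54272091), a haematopoietic cytokine gene, and sites in Il10, an anti-inflammatory cytokine gene, Il18rap, a receptor chain for interleukin 18, and Cxcr3, a chemokine receptor gene of T helper 1 cells. None of the 26 list tests passed 0.05 for Foxp3, whereas 7 did for the split by number, and effector cytokine genes had 2 of 19 with a WT only region and 1 of 19 with an IkE5 only region.

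**Figure D1:**
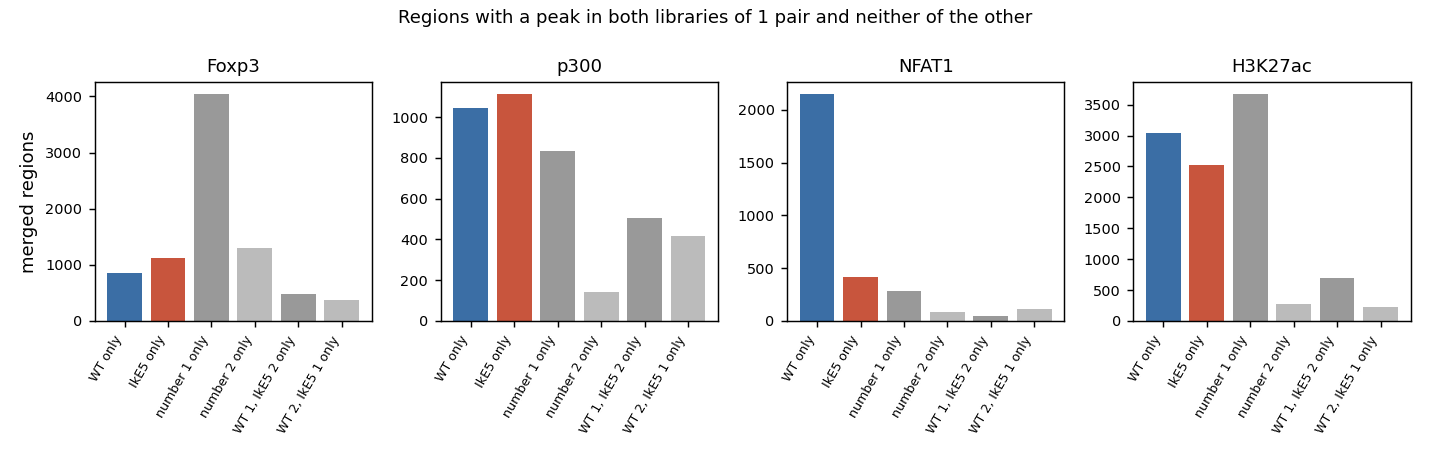
Bars give the number of merged regions, on a separate vertical axis per target, with a peak in both libraries of 1 pair and in neither of the other pair, for Foxp3, p300, NFAT1 and H3K27ac. Blue and red bars split the 4 libraries by genotype and grey bars by number or crosswise; the NFAT1 WT only bar (2152) is well above every other bar of its panel, while for Foxp3 the number 1 only bar (4048) is above both genotype bars.

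The coactivator p300 had additional sites at cytokine genes of effector T cells in the IkE5 libraries. Of the 20 genes of the list, 10 and 9 had a p300 peak in the WT libraries and 12 and 11 in the IkE5 libraries. Of 14 effector cytokine genes with any p300 region, 7 had an IkE5 only region and 0 had a WT only region. The 7 were Ifng, the gene of interferon gamma, Il2, the T helper 2 cytokine genes Il4 and Il13, Il3, and Tnfsf8 and Tnfsf14, which encode ligands of the tumour necrosis factor family. Among all other genes with a p300 region 8.51% had an IkE5 only region, an odds ratio of 10.8 with an adjusted p of 0.00172 by Fisher's exact test, and random lists matched on regions per gene held 1.33 such genes on average and as many as 7 at a share of 1e-04, the smallest that 10000 lists can give. Counted over regions, 26.9% of the list's p300 regions were IkE5 only (odds ratio 5.79, adjusted p = 0.0173). Il4, Il13 and Il3 lie close together on chromosome 11, from 53612460 to 54267279. Fisher's exact test and the matched lists count them as independent genes, so they may overstate the excess. In the other splits the same list had 2 genes on one side and 0 on the other. Whether the list passed 0.05 depended on the libraries kept. Without IkE5 replicate 1 the odds ratio was 4.32 (adjusted p = 0.212) and without IkE5 replicate 2 it was 4.21 (adjusted p = 0.0718), and within number 1 it was 3.16 (adjusted p = 0.154) and within number 2 it was 4.31 (adjusted p = 0.0477).

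At Ifng (chr10:118441046-118445894) the IkE5 only p300 region lay at chr10:118435027-118435564, 5.48 kb before the lower-coordinate end of the gene. An H3K27ac region at chr10:118434042-118436515 was likewise present in both IkE5 and in neither WT library, and NFAT1 and Foxp3 each had a peak there in 1 IkE5 library. The intragenic p300 and NFAT1 regions of Ifng, at chr10:118442809-118443373 for p300, were present in all 4 libraries of each target. At Il2 (chr3:37120713-37125954) the IkE5 only p300 region lay 0.476 kb before the lower-coordinate end, at chr3:37119511-37120236, whereas the p300 region at chr3:37125766-37126408, where both Ikaros libraries had a peak, was present in all 4. A site 4.17 kb beyond the higher-coordinate end of Il3 was IkE5 only for every target mapped in both genotypes. There p300 lay at chr11:54271451-54271973, Foxp3 at chr11:54271371-54272091, NFAT1 at chr11:54271580-54272171 and H3K27ac at chr11:54270243-54273281. At Tnfsf14 the p300 region (chr17:57182683-57183297) and an NFAT1 region (chr17:57182733-57183256) were both IkE5 only, and the same held at Cxcr3 (chrX:101729973-101730475 for p300).

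**Figure D2:**
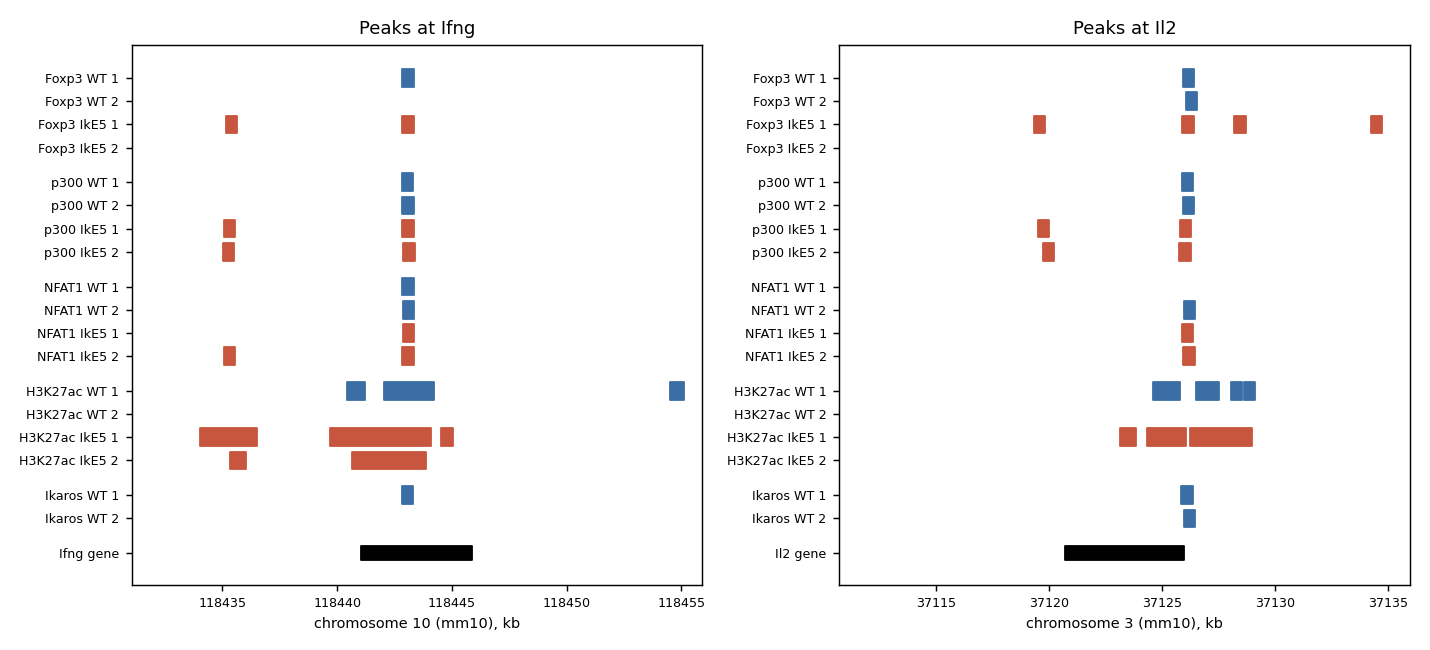
Each box is a peak, drawn to scale along the chromosome in kb, in 1 library per row at Ifng and at Il2 with 10 kb on each side; blue rows are WT, red rows IkE5 and the black bar is the gene. At 5.48 kb before the lower-coordinate end of Ifng, p300 and H3K27ac boxes appear in both IkE5 rows and in no WT row, and at 0.476 kb before that of Il2 p300 boxes appear in both IkE5 rows only.

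For p300 as a whole the numbers of peaks were 10116 ± 1896 in WT and 10321 ± 1908 in IkE5 (SD, n = 2 each, exact permutation p = 0.667). There were 1045 WT only and 1115 IkE5 only regions, more than the 836 and 143 of the split by number and the 506 and 419 of the crossed split, and 4239 regions were in all 4 libraries. WT only regions included 1 in Ikzf1 (chr11:11766020-11766594), and in or within 10 kb of the gene 5 at Foxp1 (with 2 IkE5 only), a pair at Runx1, a partner of Foxp3 (with 1 IkE5 only), and a pair at Mta2, a subunit of the NuRD corepressor that binds Ikaros. IkE5 only regions included sites in Nfatc2, the gene of NFAT1, in Il1rl1, the receptor for interleukin 33 on tissue Treg cells, in Il18rap and in Rora, a nuclear receptor of T helper 17 cells, which had 2 IkE5 only and 3 WT only regions. WT only regions lay within 2 kb of the end of a gene at 39.0% and IkE5 only regions at 22.4%. Of the other lists, 5 of 18 genes of the T helper 2, T helper 17 and follicular programmes had an IkE5 only region (adjusted p = 0.166), and Il4 and Il13 belong to both lists. The Treg signature had 3 of 28, the T helper 1 programme 3 of 14, and housekeeping genes 1 of 14.

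NFAT1, the factor that calcium signals send to the nucleus and that pairs with Foxp3 on DNA, had fewer called peaks in IkE5 cells. Lower depth or enrichment of these libraries cannot be told apart from weaker binding. Its lists held 7338 ± 689 peaks in WT and 4172 ± 1042 in IkE5 (SD, n = 2 each), 56.1% of the WT number, with both IkE5 lists shorter than both WT lists (exact permutation p = 0.333, the smallest possible here). Of 5301 regions with NFAT1 in both WT libraries, 2152 (40.6%) had no peak in either IkE5 library, and only 412 regions were IkE5 only. The other splits gave at most 280 regions on a side. WT only regions included sites in Entpd1 (chr19:40707971-40708941), which encodes the ectonucleotidase CD39, in Ikzf4, an Ikaros relative of Treg cells, in Sin3a, a corepressor subunit, and in Tox, a transcription factor gene of exhausted T cells. Others lay outside but within 10 kb of Ikzf3 and of Maf, a transcription factor gene of helper T cells, and 6 sites lay in or within 10 kb of Foxp1, which also had 1 IkE5 only site. The widest was in Slc25a51 (chr4:45408744-45409785), followed by sites in Arhgef3, Cnksr3 and Nr1d1, where width marks peaks that overlap less and not a stronger site.

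The IkE5 only NFAT1 sites again included cytokine genes. Il3, Il4 (chr11:53618547-53619174) and Tnfsf14 were the 3 of 11 effector cytokine genes with an IkE5 only NFAT1 region, against 4.57% of other genes (odds ratio 7.83, adjusted p = 0.0631), and 0 of 11 had a WT only region against 31.2% of other genes (adjusted p = 0.0736). Neither passed 0.05. An IkE5 only region also lay 2.21 kb beyond the higher-coordinate end of Pdcd1 (chr1:94054762-94055273), in Il2ra (chr2:11651409-11651912), in Ikzf2, which encodes the Ikaros relative Helios, and in Icos, a costimulatory receptor gene. Naive and quiescence genes had a WT only region in 13 of 18 (odds ratio 5.79, adjusted p = 0.0102). The excess was, however, not seen over regions (18.1% WT only, odds ratio 0.917) or against matched lists (9.87 genes on average, and 13 or more in a share of 0.0787). Of the Treg signature, 7 of 24 genes had a WT only and 4 an IkE5 only region, and of co-inhibitory and exhaustion genes 8 of 18 and 4. Most of the 2564 genotype-specific regions of NFAT1 and the 2160 of p300 did not overlap each other. Where they did, 384 pairs had the same direction and 22 opposite directions, against 15 and 8 for the split by number.

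H3K27ac, a mark of active enhancers and promoters, was missing in IkE5 cells from many regions of the genes that keep T cells resting. Of 20 naive and quiescence genes 13 had a WT only region, against 13.2% of other genes (odds ratio 12.2, adjusted p = 3.07e-06 by Fisher's exact test), and matched lists held 7.32 on average and 13 or more in a share of 0.0019. Over regions, 74 of the list's H3K27ac regions were WT only (odds ratio 4.24, adjusted p = 2.16e-20) and 3 were IkE5 only (odds ratio 0.170, adjusted p = 0.000714). In or within 10 kb of the gene there were 22 WT only regions at Foxp1, 15 at Bach2, a repressor of effector genes, 12 at Lef1, a factor of naive T cells, 9 at Satb1, a chromatin organiser of Treg development, and 6 at Foxo1, which sustains lymph node homing. Single regions were found at Tcf7, Il7r, Klf2, Id3, Btg1, Il6st and Bcl11b, and Pecam1 had 3. The 3 IkE5 only regions were at Bach2, Il7r and Id3, and the log2 difference in covered length of Il7r was 0.20 (IkE5 over WT, limma adjusted p = 0.860). Over regions the odds ratio was 2.97 within number 1 and 3.68 within number 2, while in the split by number it was 0.389 on the side of number 1 (adjusted p = 0.0149) and 1.67 on the side of number 2 (adjusted p = 1). Counted over genes, the same list also passed in the split by number with 3 of 20 (adjusted p = 0.0199) and in the crossed split with 4 of 20 (adjusted p = 0.00507). With gene ends alone 4 of its genes had a WT only region and the call ended (adjusted p = 0.0674).

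**Figure D3:**
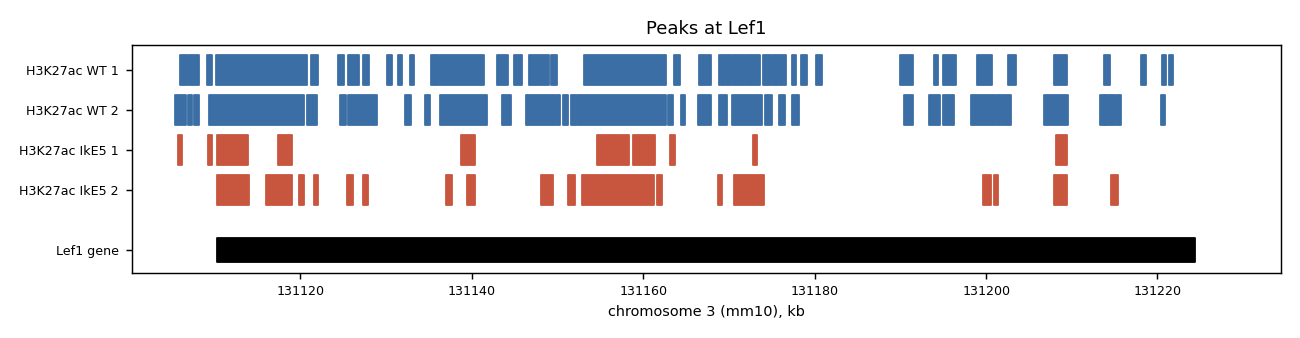
Boxes are H3K27ac peaks of the 4 libraries in and around Lef1 on chromosome 3, drawn to scale in kb, with WT in blue, IkE5 in red and the gene as a black bar. H3K27ac covered 62.2 kb on average in the WT rows and 22.9 kb in the IkE5 rows.

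Some effector cytokine genes had H3K27ac regions in IkE5 cells only. Of 18 genes 6 had an IkE5 only region, namely Ifng, Il3, Il4, Il13, Csf2 (chr11:54247807-54252148), which encodes granulocyte-macrophage colony-stimulating factor, and Tnfsf11, which encodes RANKL and had 4, and 0 had a WT only region. Over genes this did not pass (odds ratio 3.96, adjusted p = 0.0974), over regions it did (10.8%, odds ratio 2.99, adjusted p = 0.0424), and matched lists held 2.09 on average and 6 or more in a share of 0.0102. Il4, Il13, Csf2 and Il3 lie close together on chromosome 11, which neither Fisher's exact test nor the matched lists allow for. Il4 and Il13 share a single region at chr11:53626119-53627920, which overlaps neither of their IkE5 only p300 regions, and Il2, Tnfsf8 and Tnfsf14 had an IkE5 only region of p300 and none of H3K27ac. Partners of Foxp3 and NFAT had a WT only region in 11 of 24 genes (adjusted p = 0.00134), but matched lists held 8.79 on average and 11 or more in a share of 0.195, and Lef1, Tcf7, Foxo1 and Bcl11b are members of this list too. Genes of the Ikaros family and its corepressors had 0 of 178 regions WT only (adjusted p = 0.00392) and 8 IkE5 only. The Treg signature had 6 of 30 genes with a WT only and 5 with an IkE5 only region, and activation-induced genes had 3 of 33 and 4. Markers of other cell types did not pass, with WT only regions at 4 of 14 B cell genes, 1 of 10 myeloid genes and 3 of 10 CD8 and NK cell genes, and IkE5 only regions at 2, 0 and 0. Genome-wide there were 3039 WT only and 2526 IkE5 only regions, against 3677 and 270 in the split by number, and 20229 in all 4 libraries. The widest WT only region lay in Hdac9 (chr12:34555194-34563171), which encodes a histone deacetylase, and the widest IkE5 only region 14.1 kb from Iigp1 (chr18:60352044-60359558), an interferon-induced GTPase gene. WT only and IkE5 only regions lay within 2 kb of the end of a gene at 9.08% and 10.3%, against 42.3% of the regions in all 4.

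The length of chromatin covered by H3K27ac per gene gave the same genes a size. Lef1 had 62.2 ± 3.11 kb in WT and 22.9 ± 9.23 kb in IkE5 (SD, n = 2 each), a log2 change of -1.49 ± 0.34 (SE) with a limma adjusted p of 0.0922 over all 12718 genes. Foxp1 fell by 0.97 on the log2 scale (limma adjusted p = 0.0359), from 214 ± 41.6 to 110 ± 1.36 kb. Bach2 had 164 ± 19.3 and 92.3 ± 25.6 kb (limma adjusted p = 0.158). Tnfsf11 rose by 1.67 (limma adjusted p = 0.0168), from 5.18 ± 2.43 to 18.1 ± 0.415 kb, and Socs2, a cytokine signalling inhibitor gene of the Treg signature, by 1.35 (limma adjusted p = 0.0253). Runx3, a Foxp3 partner and T helper 1 factor, had 7.72 ± 0.0757 and 18.7 ± 2.14 kb (limma adjusted p = 0.0587). Foxp3 had 20.5 kb in both genotypes, with a log2 difference of -0.03, and Il2ra, Ctla4 and Ikzf1 had differences of 0.00, 0.08 and 0.13. Adjusted over the list alone, 6 effector cytokine genes were higher in IkE5 (Ifng, Il4, Il13, Csf2, Il3 and Tnfsf11), 4 naive and quiescence genes were lower (Lef1, Bach2, Foxp1 and Dapl1), Runx3 and Socs2 were higher, and the B cell gene Ebf1 and the housekeeping gene Ppia were lower. In the split by number 5 genes passed in the same way, the effector cytokine genes Il2, Tnfsf14 and Il24, and Cd200 and Rcan1.

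**Figure D4:**
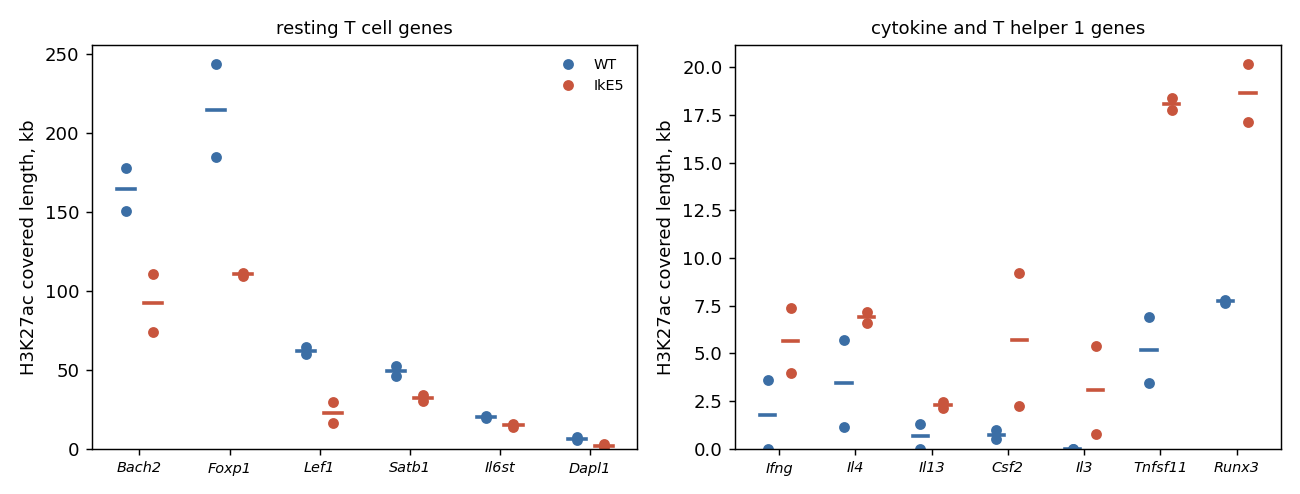
Points give the H3K27ac covered length in kb, per library, in each gene with 10 kb on each side, and short bars the mean of the 2 libraries, for WT in blue and IkE5 in red. All 6 resting T cell genes shown, picked from the naive and quiescence list, have both IkE5 points below both WT points. Others of that list, such as Klf2 and Il7r, do not. All cytokine and T helper 1 genes shown, among them Tnfsf11 (18.1 against 5.18 kb) and Runx3 (18.7 against 7.72 kb), have both IkE5 points above both WT points.

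Over all genes limma called 88 higher and 45 lower in IkE5, and 0 in either direction for the 2 other splits. An unadjusted limma p under 0.05 was found for 809 and 814 genes by genotype, 565 and 426 by number and 8 and 38 in the crossed split. In the other splits any genotype difference adds to the spread within groups, so their 0 calls are no measure of false calls. Genes with the largest increases, chosen after their values were seen, included Ifitm1 (log2 3.26, limma adjusted p = 0.00137) and Ifitm3 (2.76), interferon-induced membrane genes, Gas7 (3.35) and Plac8 (2.85). The largest decreases included Ms4a4a (-2.78), Hdac9 (-2.49) and Sesn1 (-1.77), a stress-response gene under FoxO control. The counts depended on the model. Without scaling to total covered length limma called 0 genes in either direction, with a filter at 5 kb 19 higher and 7 lower, and with the library number as a block 635 higher and 614 lower. By list, the median log2 difference was 0.77 for effector cytokines (14 of 15 genes higher), 0.48 for the T helper 1 programme (19 of 22), -0.28 for naive and quiescence genes (19 of 20 lower), -0.02 for the Treg signature, 0.00 for activation-induced genes, 0.04 for co-inhibitory genes and -0.24 for the 5 CD8 and NK cell genes measured. The 2-sided share of random lists with a median as far out was 2e-04 for effector cytokines and the T helper 1 programme, the smallest they can give, and 0.001 for naive and quiescence genes. Among effector cytokines Il4, Il13, Csf2 and Il3 are neighbours, which the random lists do not copy. Without a genotype contrast this test called even more lists, 6 of the 13 in the split by number against 4 by genotype, among them the Treg signature (-0.15) and co-inhibitory genes (-0.25). Effector cytokines, the T helper 1 programme and naive and quiescence genes also differed between the libraries numbered 2 and 1, with medians of -0.60, -0.28 and 0.29. These were smaller in size than the genotype medians for the first pair of lists and not for naive and quiescence genes. Random lists had medians of 0.10, 0.11 and 0.07 by number and of -0.01, -0.02 and -0.02 by genotype. Set against those, naive and quiescence genes too moved somewhat less by number than by genotype. Within number 1 and number 2 the genotype medians were 0.61 and 0.63 for effector cytokines, 0.51 and 0.32 for the T helper 1 programme and -0.14 and -0.39 for naive and quiescence genes. The effector cytokine median depended on the genes and libraries kept. It was 0.0451 (share of random lists 0.709) for genes with at least 5 kb covered and ranged from 0.15 to 1.65 with 1 library left out. The T helper 2, T helper 17 and follicular list had a median of 0.35, and -0.05 (share of random lists 0.738) without the cytokine genes it shares. Medians of the remaining lists were 0.05 for the Ikaros family and corepressors, -0.10 for partners of Foxp3 and NFAT, 0.03 for B cell, -0.15 for myeloid and -0.07 for housekeeping genes, and none passed.

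Whether the sites that differed were those bound by Ikaros was asked by comparing WT regions with and without an Ikaros peak, by Fisher's exact test over regions. Foxp3 regions with Ikaros were absent from both IkE5 libraries at 5.40% and those without at 22.4% (odds ratio 0.198, Fisher p = 1.17e-86), p300 regions at 14.2% and 19.6% (odds ratio 0.678, p = 1.99e-06), and H3K27ac regions at 2.07% and 22.3% (odds ratio 0.0736). NFAT1 went the other way, with 42.3% of 3879 regions with Ikaros and 35.9% of 1422 without (odds ratio 1.31, p = 2.31e-05, Fisher's exact test over regions). Over both sides of the splits by number and crosswise the odds ratios ranged from 0.0593 to 0.193 for Foxp3, from 0.359 to 0.735 for p300, from 0.0420 to 0.147 for H3K27ac and from 0.461 to 0.691 for NFAT1, so a lower loss at Ikaros sites was also found without a genotype contrast. The NFAT1 direction turned with an Ikaros peak in either library (0.561), without WT Ikaros replicate 2 (0.462) and without WT NFAT1 replicate 2 (0.953). For p300 stratifying by how many other targets lay at the region gave 1.11, not past 0.05. Of the regions with a peak in both IkE5 libraries and with Ikaros, 3.34% were IkE5 only for Foxp3, 9.10% for p300, 6.55% for NFAT1 and 0.923% for H3K27ac, in each case a lower share than of the regions without Ikaros. The odds ratios were 0.0611, 0.162, 0.169 and 0.0401. Ikaros was mapped in WT cells only, so values under 1 and under those of the other splits are expected here by construction, and nothing is drawn from them. For the same reason the odds ratios of WT regions, 1.31 for NFAT1 among them, may lie above those of the other splits.

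The share of p300, NFAT1 and H3K27ac peaks that overlapped a Foxp3 peak of the same genotype and number was measured last. It was 75.1% ± 17.5 in WT and 71.2% ± 16.8 in IkE5 for p300, 69.7% ± 21.4 and 66.0% ± 26.1 for NFAT1 and 34.2% ± 4.22 and 35.9% ± 2.14 for H3K27ac (SD, n = 2 each, exact permutation p = 0.667 for each). For p300 the spread went with the Foxp3 lists, since those numbered 1 overlapped 83.1% to 89.7% of p300 peaks and those numbered 2 58.5% to 62.8%. Within number 1 and number 2 the IkE5 share differed from the WT share by -4.42 and -3.48 percentage points for p300, -0.387 and -7.01 for NFAT1 and 3.18 and 0.230 for H3K27ac. Against a single set of Foxp3 regions, those of both WT libraries, the p300 share was 56.0% and 60.2% in WT and 47.9% and 48.2% in IkE5, and the NFAT1 share 53.1% and 53.5% in WT and 39.3% and 38.6% in IkE5, with both IkE5 values under both WT values (exact permutation p = 0.333). This set, called in WT alone, favours WT peaks by construction. The H3K27ac share did not separate, with 19.3% and 28.3% in WT and 20.5% and 26.7% in IkE5.

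At Ikzf1 (chr11:11684962-11772930) peaks in IkE5 cells do not check the labels, because the alteration behind the IkE5 name is not given in the sources used here. H3K27ac covered 70.6 kb in WT and 78.7 kb in IkE5 around this gene. A site 5.63 kb before its lower-coordinate end (chr11:11678814-11679331 for p300, chr11:11678802-11679309 for NFAT1) and bound by Ikaros itself was WT only for p300 and NFAT1 and held Foxp3 in all 4 libraries. Inside the gene, p300 at chr11:11731605-11732110 and NFAT1 at chr11:11731669-11732272 were IkE5 only. At Ctla4 (chr1:60909025-60915832), a gene of Treg suppression, p300 and NFAT1 shared a site 6.01 kb before the lower-coordinate end (chr1:60902451-60903011 for p300) in all 4 libraries, and at Pdcd1 3 of 4 NFAT1 regions were in all 4.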

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

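The alternatives for gene lists, covered length, H3K27ac peaks wider than 500 bp, distance from gene ends and stratification were chosen after seeing the data, and the others before. Of 316 alternatives over 36 results, 212 left the direction and the side of the threshold, or the count within 1.5 times, as reported. The 212 include the library number as a block for peak numbers, region counts and shares at Foxp3 peaks, which could not change by construction. The cause of the changes below was not tested unless the construction of the alternative gives it. With regions cut to fixed 500 bp windows there were 4001 IkE5 only H3K27ac regions in place of 2526. An Ikaros peak in either library turned the odds ratio of NFAT1 loss to 0.561, stratification turned that of p300 to 1.11, and a single set of WT Foxp3 regions turned the difference in the H3K27ac share at Foxp3 to -0.194 percentage points.

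Within number 1 there were 8 list calls for Foxp3 and 4 for NFAT1, within number 2 there were 4 for p300, 6 for NFAT1 and 7 for H3K27ac, and with the nearest gene within 100 kb there were 2 for Foxp3, 2 for p300, 4 for NFAT1 and 4 for H3K27ac. Gene ends with 2 kb on each side gave 0 for NFAT1 and 0 for H3K27ac, and counting over regions gave 0 for NFAT1 and 5 for H3K27ac. For p300 at effector cytokine genes the odds ratio was 10.7 with gene ends and 3.16 within number 1, neither past 0.05. For H3K27ac at the same genes it passed 0.05 over regions (2.99), within number 2 (3.40) and with peaks wider than 500 bp (5.40). For H3K27ac at naive and quiescence genes it was 8.20 with gene ends, no longer past 0.05. For NFAT1 at naive and quiescence genes it turned to 0.917 over regions and 0.631 with gene ends.

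For H3K27ac covered length limma called 42 genes higher and 19 lower with a pseudocount of 200 bp, 54 and 24 with no filter, 19 and 7 with a filter at 5 kb, and 0 and 0 without scaling. With that filter the effector cytokine median was 0.0451 (share of random lists 0.709) and that of the T helper 2, T helper 17 and follicular list 0.19 (0.055), with fewer genes left.

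Leaving out a library relaxes the definition of a genotype-specific region, so all such counts grow by construction. WT only regions ranged from 1807 to 4350 for Foxp3, 1563 to 3397 for p300, 2344 to 4206 for NFAT1 and 4347 to 15857 for H3K27ac, and IkE5 only regions from 2030 to 5940, 1396 to 3938, 550 to 1258 and 2858 to 12348. The log2 ratio of peak numbers ranged from -0.10 to 0.23 for Foxp3, with -0.09 without WT replicate 2 and -0.10 without IkE5 replicate 1, and from -0.16 to 0.22 for p300, with -0.16 without either of these. It ranged from -0.33 to 0.26 for H3K27ac, with 0.26 without WT replicate 1 and 0.15 without IkE5 replicate 2. The odds ratio of loss at Ikaros sites ranged from 0.173 to 0.910 for p300 and from 0.462 to 1.47 for NFAT1, with 0.953 without WT NFAT1 replicate 2 and 0.462 without WT Ikaros replicate 2. List calls ranged from 0 to 5 for Foxp3, 0 to 4 for p300, 2 to 5 for NFAT1 and 2 to 5 for H3K27ac. The odds ratio at effector cytokine genes ranged from 4.21 to 7.59 for p300 and from 2.35 to 4.45 for H3K27ac, and that of NFAT1 at naive and quiescence genes from 3.91 to 7.17. The difference in the share at Foxp3 peaks ranged from -16.3 to 8.40 points for p300, with 8.40 without WT replicate 1 and 7.92 without IkE5 replicate 2, from -22.1 to 14.7 for NFAT1, with 11.4 and 14.7, and from -1.28 to 4.69 for H3K27ac. Genes called for covered length ranged from 59 to 343 higher and from 30 to 297 lower, with the lone library assumed to vary like the other group, and list medians from 0.15 to 1.65 for effector cytokines, 0.0270 to 0.44 for the T helper 2, T helper 17 and follicular list, and -0.47 to -0.0877 for naive and quiescence genes.

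By the labels, WT and IkE5 libraries share only a number. Lists numbered 1 were nevertheless longer than those numbered 2 in both genotypes for Foxp3, p300, NFAT1 and H3K27ac. Same-numbered Foxp3 lists overlapped at 67.5% of peaks on average, against 59.1% within a genotype. For p300, NFAT1 and H3K27ac the overlap was higher within a genotype. Whether the number marks a shared preparation is not known, and the exact permutation p-values leave out any such pairing. The correlation of same-numbered libraries in their deviations was 0.27 for Foxp3, -0.05 for p300, 0.02 for NFAT1 and 0.02 for H3K27ac. With the number as a block limma called 635 genes higher and 614 lower in covered length. For peak numbers and shares the mean paired difference equals the unpaired one by construction (a log2 ratio of -0.83 for NFAT1). Stricter score thresholds, the strongest peaks, strata of peak score, distance to transcription start sites and motif content were not run, since they need scores, strand or sequence. Read depth is unknown, so a peak missing from a list shows that it was not called, not that binding was absent.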

Other observations

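The tests in this part were chosen after the results were seen, except for the gene lists of NK cell, CD8 T cell and Treg genes, which had been fixed before. Some genes picked for the size of their H3K27ac difference are induced by interferons. Ifitm1, Ifitm3 and Ifitm6 (log2 2.40) are neighbours in a single cluster, wide IkE5 only regions lay near Iigp1 and Ifi27l2b, and Iigp1 rose by 1.29 (limma adjusted p = 0.0288). A list of 50 other interferon-induced genes was therefore written after these were seen and before the others were tested, on the hypothesis that they too carry more H3K27ac in IkE5 cells. Of 45 measured, 34 were higher in IkE5, with a median log2 difference of 0.21 against -0.02 for random lists (2-sided share of random lists as far out 2e-04, the smallest they can give), and 0 passed limma on their own. The 11 lower genes included Rsad2 (-0.67), Usp18 (-0.33), Ifit1 (-0.29), Cxcl10 (-0.29), Ifit3 (-0.28) and Oasl1 (-0.25), and the highest were Ifih1 (0.85) and Nlrc5 (0.65), all chosen after their values were seen. Some members are neighbours and share regions, which the random lists do not copy. The median was 0.27 within number 1 and 0.10 within number 2. In the split by number it was -0.00 against 0.11 for random lists (share 0.0354), and in the crossed split 0.05 against 0.02 (share 0.207). Without the T helper 1 genes it was 0.21 over 42 genes, and -0.02 against 0.12 for random lists in the split by number (share 0.0106). A stronger interferon response of the IkE5 cells may underlie the median, but with such genes among the lower ones this stays a hypothesis.

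The largest decreases in covered H3K27ac included Sesn1 and Prg4. Sesn1 had 23.0 and 21.7 kb in WT and 5.59 and 6.41 kb in IkE5, and Prg4 12.8 and 11.5 kb against 2.59 and 2.94 kb. These are values chosen for their size.

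Most genotype-specific regions of a target overlapped none of another target, but those that did mostly had the same direction. On the hypothesis that this holds for p300 and NFAT1, 94.6% of their overlapping pairs of genotype-specific regions had the same direction, against 65.2% of 23 pairs in the split by number. These are the pairs already counted above, so the hypothesis was not tested on new regions. A share also depends on how many regions each side holds. As an odds ratio the values were 837.5 by genotype and 1.17 by number, and for Foxp3 and p300 798 and 2.36. For p300 and H3K27ac it was 134 in the same and 6 in opposite directions (29 and 6 by number), for Foxp3 and p300 218 and 7 (157 and 25 by number), and for NFAT1 and H3K27ac 91 and 8 (5 and 9 by number). Foxp3 and H3K27ac had 160 and 24, and 332 and 15 in the split by number, so for this pair a shared direction is no mark of genotype.

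The shorter NFAT1 lists of IkE5 cells were weighed against lower depth or enrichment of these libraries. If that were the whole cause, and sites were equally strong, NFAT1 would be missing as often at p300 regions of either genotype. It was missing at 82.8% of 302 regions where p300 was WT only and at 48.8% of 41 where p300 was IkE5 only (odds ratio 5.05, p = 5.13e-06 by Fisher's exact test). At regions with p300 in no library, however, 77.7% of 224 were missing too, about as many as where p300 was WT only, as weak sites under a lower depth would be. At regions with p300 in all 4 libraries 21.9% of 2996 were missing. Lower depth and weaker NFAT1 binding in IkE5 cells cannot be told apart at any of these regions, because the lists give no site strength.

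The IkE5 only p300 regions at effector cytokine genes were weighed against 3 explanations. IkE5 lists that are more sensitive at every gene are argued against by the matched random lists (a share of 0.0001 held as many such genes, the smallest they can give) and by a ratio of peak numbers of 1.02. The random lists do not copy that Il4, Il13 and Il3 are neighbours. CD8 T or NK cells among the IkE5 cells were weighed by the share of their marker genes with an H3K27ac peak, 64.3% ± 10.1 in WT and 42.9% in both IkE5 libraries (a difference of -21.4 points). Cd8a had 1.38 kb covered in WT and 0 in IkE5. Of that list of 14 genes only 5 were long enough for the covered-length test, with 2 higher and 3 lower in IkE5 (share of random lists 0.127). Other genes that such cells express, picked after their values were seen, went both ways from WT to IkE5. Mean covered length rose at Klrg1 (7.77 to 22.3 kb) and Nkg7 (5.50 to 7.98 kb) and fell at Cd8b1 (1.82 to 1.11 kb) and Klrb1c (2.68 to 2.19 kb). With so many genes of the list near the floor, the lower share cannot decide whether such cells were present. Conventional T cells or another mix of Treg subsets may still be a source, since the Treg signature had a median of -0.0216 and a small share of such cells would not move it; this cannot be told apart from a direct effect of the genotype.

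The WT only H3K27ac regions at naive and quiescence genes were weighed in the same way. Many regions per gene as the whole cause is argued against by the matched lists (a share of 0.0019), and less sensitive IkE5 lists by number 2, where the IkE5 list covers more (62.1 against 54.6 Mb) and regions of the list were still WT only more often (odds ratio 3.68). Another mix of naive and activated Treg cells may be the source and cannot be told apart from a direct effect of genotype. The list's covered length also differed between the libraries numbered 2 and 1, by a median of 0.287 against 0.0719 for random lists. The mix of cells could therefore vary between preparations of 1 genotype too.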
